A study of Mus musculus with 6 samples.

How the data were processed

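RNA from splenic CD4+ T cells of lean and obese C57BL/6 mice was sequenced on an Illumina HiSeq, per the labels' protocols, with 3 libraries per group. The authors deposited 1 table per library with a gene number, a symbol and an FPKM value of 2 decimals. FPKM values in the deposited tables are fragments mapped to a gene, scaled by transcript length and by the mapped fragments of the library. Bowtie and RSEM, with builds GRCm38 and mm10, are named without versions per the submitters' processing notes. Filters, annotation release and strandedness are not given in the sources used here. Each table held 22899 genes, of which 1116 had no symbol, and 21633 gene numbers were found in the RefSeq table of assembly GRCm38.p6, from which coordinates were taken.

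FPKM is relative to the mapped fragments of a library, so a few abundant transcripts can lower the values of all others. Expected counts, for which a count-based test had been planned as the main test, were not among the values used here, so the planned test for FPKM was run. To look for depth, low FPKM values times transcript length, less an assumed fragment length of 150, 200 or 250 bases, were searched for whole-read steps. The step score, which has a maximum of 1, was 0.076 to 0.156, against 0.876 to 0.904 for simulated whole reads at the same lengths, so depth stayed unknown. Precision is therefore given only by the spread between libraries.

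Samples were assigned to groups by the diet and state given in the labels. Values were transformed to log2(FPKM + 1), and the 10788 genes with at least 1 FPKM in at least 3 of the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with the group as the sole term and no further scaling. Tests were 2-sided. BH-adjusted p stands for a p-value with Benjamini-Hochberg adjustment, and genes under 0.05 were called. Fold differences are obese minus lean on the log2(FPKM + 1) scale. Their SE is that of limma, from a variance pooled over both groups and drawn towards the intensity trend over all genes. Gene lists, 40 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01 where at least 5 members were tested, which held for 36, with BH adjustment over the lists. Each was also tested with a correlation estimated from the data, and counts of members were also adjusted over the list alone. With the estimated correlation camera also uses fewer degrees of freedom, so a lost call need not come from correlation between genes.

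The test, the filter, the lists, the rule for named genes and all alternatives listed below other than those said to be added were fixed before the data were examined. Named genes were the 10 largest rises and 10 largest falls among called genes with non-overlapping groups and a higher group mean of at least 5 FPKM, without predicted genes; up to 4 called members of each list with the smallest adjusted p, or the 2 members with the smallest p where none was called; and a fixed set of T cell and metabolic genes whatever the result. Some genes that this rule names are not reported here, and counts over named genes leave them out.

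Alternatives were another pseudocount, other filters, median-of-ratios, quantile and TPM scaling, scaling without immunoglobulin, haemoglobin and mitochondrial genes, a 2-fold minimum, other variance models, library weights, the replicate number as a block, each library left out in turn, an estimated inter-gene correlation and fry. The scaling without immunoglobulin, haemoglobin and mitochondrial genes left out 11 genes, none of them from the list of mitochondrially encoded genes. Covariates for B cell or erythroid markers, and the removal of other cell types' markers, were added after seeing the data. The gene test was tested on simulated data with 200 changed genes among 10788 in each of 10 runs. It recovered 56.0% of genes changed by 0.5 on the log2 scale, 98.4% at 1 and 99.9% at 2, and 6.58% of its calls were false. Unchanged simulated libraries gave a mean of 0.4 genes and 0.2 lists. The simulation held no correlation between genes, so it does not show how the list test behaves where genes move together.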

Results

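RNA was sequenced from splenic CD4+ T cells, the helper lineage of T lymphocytes, purified by flow cytometry from C57BL/6 mice. Mice were fed either a normal diet (lean) or a high-fat diet with 60 kcal% fat (obese), and each group was represented by 3 libraries. The values were FPKM (fragments mapped to a gene, scaled by its transcript length and by the mapped fragments of the library) for 22899 genes per library. The FPKM of a library summed to between 616104 and 656303 in the lean libraries and to between 595106 and 630744 in the obese ones. Genes above 0 numbered 15254 to 15284 in the lean libraries and 15501 to 16046 in the obese ones. No read counts were used here, so the sequencing depth behind each value is unknown. The labels do not say whether each library came from a separate mouse, so p-values measure the spread between these libraries.

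The libraries carried transcripts of helper T cells and, in all 6, also those of other cells. Cd4, the co-receptor that defines the lineage, stood at 339.9 ± 20.3 FPKM in lean and 309.4 ± 26.0 FPKM in obese libraries (SD, n = 3 each), with a log2 difference of −0.14 ± 0.09 (SE) that did not pass the test (limma, BH-adjusted p = 0.342). Cd3e, a subunit of the T cell receptor complex, ranged from 346.2 to 454.9 FPKM over the 6 libraries. Cd8a, the co-receptor of cytotoxic T cells, stood at 10.8 ± 2.34 FPKM in lean and 13.1 ± 3.59 FPKM in obese libraries (SD, n = 3 each), and Cd8b1, its partner chain, lay between 39.1 and 63.0 FPKM over the 6. Cd79a of B cells lay between 150.03 and 405.27 FPKM, Cd74 of antigen-presenting cells between 1560 and 3335 FPKM and Lyz2 of myeloid cells between 322.8 and 901.6 FPKM. Pearson correlations across tested genes, which are not independent replicates, were 0.989 to 0.995 within groups and 0.971 to 0.987 between groups. The first principal component held 65.4% of the variance and separated the groups, with scores of −21.7 to −15.9 for lean and 9.93 to 29.6 for obese libraries.

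The comparison of obese with lean libraries asks which transcripts of splenic CD4+ T cells differ with diet-induced obesity. Of 10788 tested genes, 678 changed, 622 of them higher and 56 lower in obese libraries. Among the largest rises were genes of red blood cells and their precursors, and among the largest falls were heat shock chaperones and granule proteins of neutrophils. At least 2-fold changes on the log2(FPKM + 1) scale were found for 199 of the higher and 17 of the lower genes. Differences on this scale understate the change of low genes. The 678 genes each had groups that did not overlap, as did 31.5% of all tested genes, against 10% by chance for 3 against 3 libraries. The median log2 difference of all tested genes was 0.10, and medians of gene lists are given relative to it. Higher genes made up 91.7% of the calls, but 71.5% (434 higher, 173 lower) after median-of-ratios scaling and 74.2% (322 higher, 112 lower) after quantile normalization. Without lean 1 the test called 326 genes, without lean 2 it called 318, and the count was 464 without obese 1 or without obese 3. The lower genes numbered 24 without lean 1, 19 without lean 2, 97 without lean 3, 22 without obese 1 and 38 without obese 2, and 28 of the 61 named genes past the threshold remained so in each of the 6 leave-one-out fits.

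All 10 tested erythroid markers rose in the obese libraries, and all 10 also passed when adjusted over the list alone. The paired alpha globin genes Hba-a1 (gene 15122, chromosome 11, 32283672 to 32284486, GRCm38) and Hba-a2, which encode a chain of haemoglobin, together stood at 171.8 ± 98.8 FPKM in lean and 10917 ± 7369 FPKM in obese libraries (SD, n = 3 each). The beta globin genes Hbb-bs and Hbb-bt together rose from 105.9 ± 65.1 to 7823 ± 5450 FPKM (SD, n = 3 each). Reads can be shared between such near-identical copies, so the values of single copies are uncertain. Globins took 0.0258% to 0.0710% of the summed FPKM in lean libraries, and 4.56%, 0.702% and 3.90% in obese 1, obese 2 and obese 3. Slc4a1, the anion exchanger of the red cell membrane, rose from 0.810 ± 0.403 to 88.7 ± 61.6 FPKM (SD, n = 3 each), a log2 difference of 5.26 ± 0.61 (SE; limma, BH-adjusted p = 0.00182). Alas2, the first enzyme of haem synthesis in red cell precursors, rose by 4.70 ± 0.63 on the log2 scale (SE; limma, BH-adjusted p = 0.00350). Tmcc2, Cldn13 and Rhd, the last a red cell blood group protein, were also among the 10 largest rises, with log2 differences of 4.59, 3.43 and 3.42. The list had a relative median of 4.88 and passed with camera (BH-adjusted p = 2.55e-10), but not with an estimated correlation (BH-adjusted p = 0.315).

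Of 17 tested monocyte and macrophage markers, 15 rose and none fell, and 16 rose when adjusted over the list alone. C1qa, C1qb and C1qc, neighbouring genes on chromosome 4 that encode the chains of complement C1q and are made mainly by macrophages, rose together. C1qb (gene 12260, 136880126 to 136886200, GRCm38) stood at 59.1 ± 1.16 FPKM in lean and 162.6 ± 22.9 FPKM in obese libraries (SD, n = 3 each), a log2 difference of 1.44 ± 0.10 (SE; limma, BH-adjusted p = 4.00e-04). C1qa and C1qc rose by 1.48 and 1.5 on the log2 scale. The mean log2 value of the list was 4.57 to 4.68 in lean and 5.74 to 5.84 in obese libraries. The relative median was 1.16 (camera, BH-adjusted p = 8.64e-18), and this was the only list that also passed with an estimated correlation (BH-adjusted p = 0.0374).

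Neutrophil and natural killer (NK) cell markers lay lower in obese libraries. Of 13 tested neutrophil markers, 6 fell and none rose, and 10 fell when adjusted over the list alone. S100a8 and S100a9, the subunits of calprotectin, fell from 142.2 ± 21.0 to 56.5 ± 25.7 FPKM and from 209.8 ± 34.0 to 82.7 ± 39.5 FPKM (SD, n = 3 each). Retnlg, a secreted protein of neutrophils, had a log2 difference of −1.36 ± 0.18 (SE; limma, BH-adjusted p = 0.00356), and the granule proteins Lcn2, Ltf and Ngp had log2 differences of −1.81, −1.82 and −1.92. Of 13 NK cell markers, 3 fell and 1 rose, and 7 fell and 1 rose when adjusted over the list alone. Klra8 and Ncr1, receptors of NK cells, had log2 differences of −0.77 ± 0.10 (SE; limma, BH-adjusted p = 0.00343) and −0.62 ± 0.14 (SE; limma, BH-adjusted p = 0.0328). Klra4, from the same receptor family as Klra8, had −0.54. The member that rose, Tyrobp (log2 difference 0.36), is an adaptor also used by myeloid cells; after median-of-ratios scaling its log2 difference was 0.21 and did not pass (limma, BH-adjusted p = 0.221). Relative medians were −1.46 for neutrophils (camera, BH-adjusted p = 5.24e-12) and −0.45 for NK cells (camera, BH-adjusted p = 2.49e-07), and both lists had a BH-adjusted p = 0.315 with an estimated correlation. Of the named markers, Retnlg and Klra8 passed in all 6 leave-one-out fits. Without lean 1 or lean 2, S100a8, S100a9, Lcn2, Ltf, Ngp, Ncr1 and Klra4 did not pass, and Ltf, Ngp, Ncr1, Klra4 and Tyrobp did not pass without further libraries, with limma BH-adjusted p up to 0.116.

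All 7 tested plasma cell markers rose when adjusted over the list alone, and 1 rose over all genes (relative median 0.54; camera, BH-adjusted p = 0.00428; BH-adjusted p = 0.633 with an estimated correlation). It was Jchain, the joining chain of secreted antibodies, with 363.8 ± 26.5 FPKM in lean and 756.0 ± 273.1 FPKM in obese libraries (SD, n = 3 each; log2 difference 0.999; limma, BH-adjusted p = 0.0252), which did not pass without any 1 of the lean libraries (BH-adjusted p up to 0.0897), and the list did not pass without lean 3 (BH-adjusted p = 0.0600). None of the 13 B cell markers or the 10 MHC class II genes passed over all genes or over the list alone. Their lists did not pass with camera (BH-adjusted p = 0.166 and 0.173), but both passed as higher without lean 2 and without obese 1, and the B cell list also without obese 2 and after median-of-ratios scaling, with BH-adjusted p down to 7.53e-05. With the erythroid marker covariate both passed as lower (camera, BH-adjusted p = 5.92e-07 and 3.63e-04). That covariate correlates with the group at 0.944, so it leaves little of the group difference to test. The B cell marker mean on the log2 scale was highest in lean 2 (5.03) and obese 3 (5.58) and lay between 4.19 and 4.72 in the other libraries. Bank1 and Ms4a1, expressed in B cells, had log2 differences of 0.85 and 0.71, and Ciita and H2-DMb1, of antigen presentation, had 0.70 and 0.49, none past the threshold. Dendritic cell and platelet markers did not pass as lists (camera, BH-adjusted p = 0.541 and 0.941) and had no called member. Over the list alone, 1 dendritic marker rose, 1 fell, and 1 platelet marker rose. Bst2 and Batf3 had log2 differences of −0.29 and 0.54, and Clec1b and Gp9 had 0.80 and 0.40. Lists with under 5 tested members were not tested: CD8 T cells (2), gamma-delta and NKT cells (2), stromal and endothelial cells (1) and mitochondrially encoded genes, of which none was found. Cd8b1, Blk and Pecam1 of these lists had log2 differences of 0.01, 0.42 and 0.04 and did not pass.

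**Figure D1:**
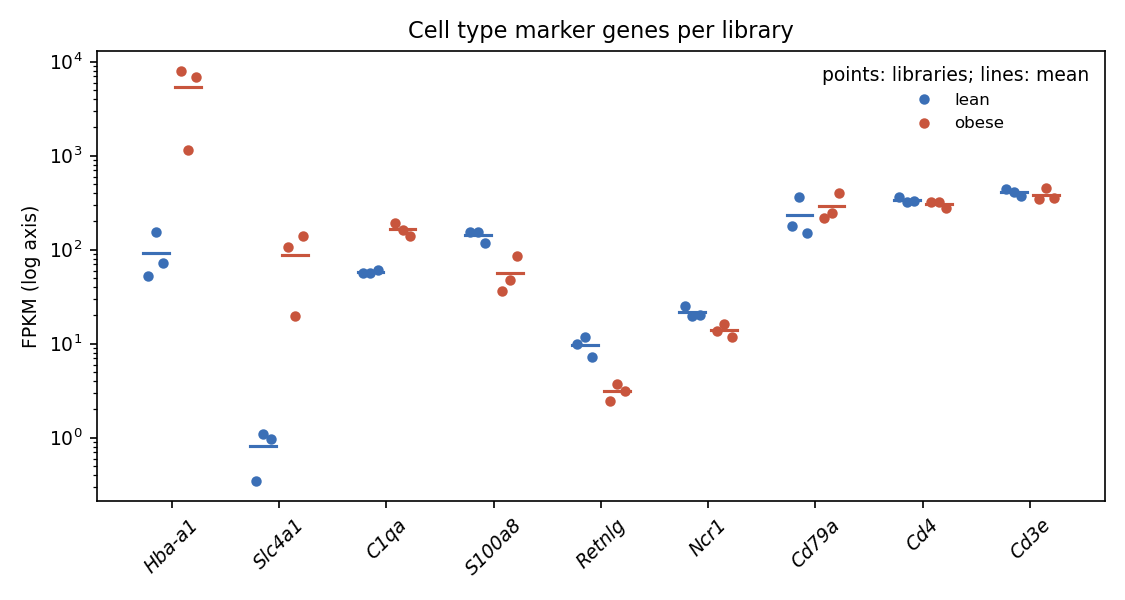
FPKM of cell type marker genes in the 6 libraries on a log axis, with points for libraries and horizontal lines for group means. Hba-a1 lay between 52.8 and 153.2 FPKM in lean and between 1153 and 7926 FPKM in obese libraries, while Cd4 lay between 279.3 and 362.6 FPKM in all 6.

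Genes of activated and memory T cells lay higher in obese libraries. Of 24 tested effector and memory genes, 5 rose and none fell, and 11 rose when adjusted over the list alone. S100a4, a calcium-binding protein of memory cells, rose from 223.0 ± 24.9 to 320.4 ± 7.89 FPKM (SD, n = 3 each), a log2 difference of 0.53 ± 0.09 (SE; limma, BH-adjusted p = 0.0116). Prdm1, a transcription factor of effector differentiation, rose by 0.79 ± 0.16 on the log2 scale (SE; limma, BH-adjusted p = 0.0252). Itgb1, an integrin chain, and Lgals3, a galectin, rose by 0.60 and 0.57. The fifth was the transcription factor Maf (log2 difference 0.58), named after its values were seen. Macrophages express these genes too, and macrophage markers were higher in each obese library, with a mean log2 value of at least 5.74 against at most 4.68 in lean libraries. Plasma cells also express Prdm1, and the mean of the plasma cell list was at least 4.97 in obese and at most 4.89 in lean libraries. Cd44, the usual surface marker of memory cells, stood at 36.6 ± 3.57 FPKM in lean and 49.5 ± 5.86 FPKM in obese libraries (SD, n = 3 each), a log2 difference of 0.42 that did not pass (limma, BH-adjusted p = 0.0538). The list had a relative median of 0.20 (camera, BH-adjusted p = 0.00720; BH-adjusted p = 0.633 with an estimated correlation) and did not pass without lean 3 (BH-adjusted p = 0.0600). After median-of-ratios scaling the limma BH-adjusted p was 0.0687 for S100a4, 0.0661 for Lgals3 and 0.0520 for Itgb1, and in leave-one-out fits S100a4 did not pass without lean 2, Lgals3 without lean 2 or obese 3, Prdm1 without lean 1 or lean 2, and Itgb1 without lean 1 or any 1 obese library (BH-adjusted p up to 0.0972).

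Of 16 inhibitory receptor and senescence-associated genes, 3 rose and none fell, and 9 rose when adjusted over the list alone. Pdcd1 (gene 18566, chromosome 1, 94038305 to 94052553, GRCm38), which encodes the inhibitory receptor PD-1, rose from 34.0 ± 2.73 to 48.4 ± 5.88 FPKM (SD, n = 3 each), a log2 difference of 0.49 ± 0.10 (SE; limma, BH-adjusted p = 0.0260). Entpd1, the ectoenzyme CD39, which macrophages and B cells also carry, rose by 0.71 ± 0.10 (SE; limma, BH-adjusted p = 0.00360), and Havcr2, the receptor TIM-3, by 0.72 ± 0.18 (SE; limma, BH-adjusted p = 0.0491). The relative median was 0.29 (camera, BH-adjusted p = 0.0347; BH-adjusted p = 0.725 with an estimated correlation). Havcr2 is also expressed by myeloid cells, and the macrophage marker mean was at least 5.74 in obese and at most 4.68 in lean libraries. The list did not pass without lean 2, lean 3 or obese 3 (BH-adjusted p up to 0.132) or with the B cell marker covariate (0.0596, with a list median of 0.36 against 0.40 without it), and Havcr2 passed in no leave-one-out fit but that without lean 3 (BH-adjusted p up to 0.153). Pdcd1 did not pass without lean 2, lean 3, obese 2 or obese 3 (limma, BH-adjusted p up to 0.0963), nor after median-of-ratios scaling (0.0603).

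No naive and quiescence gene (18 tested) and no T cell identity gene (17 tested) changed, over all genes or over the list alone, yet both lists lay lower than other genes. Their relative medians were −0.12 (camera, BH-adjusted p = 0.00720) and −0.22 (camera, BH-adjusted p = 8.90e-04), each with a BH-adjusted p = 0.633 with an estimated correlation. Before subtracting that of all genes, the medians were −0.02 and −0.12. List means overlapped between groups. The naive list stood at 6.61 to 6.67 in lean and 6.67, 6.68 and 6.46 in obese libraries. The identity list stood at 7.34 to 7.43 in lean and 7.36, 7.42 and 7.16 in obese libraries. Lef1 and Txk, of naive T cells, had log2 differences of −0.44 and −0.33 and did not pass. Il7r, of the same list, had 0.47 and did not pass either, so members of the naive list went both ways. Skap1 and Themis, of T cell receptor signalling, had −0.21 and 0.33. The naive list did not pass without lean 3 or obese 3, and the identity list did not pass without obese 3, with camera BH-adjusted p up to 0.189 and 0.1, and neither passed with the B cell marker covariate (0.210 and 0.126). With the erythroid marker covariate the identity list passed as higher (camera, BH-adjusted p = 0.0279), but that covariate correlates with the group at 0.944 and leaves little to test.

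The regulators Tbx21 (Th1), Gata3 (Th2), Foxp3 (regulatory) and Bcl6 (follicular) of helper subsets did not pass the test. Their log2 differences were −0.20, −0.02, 0.15 and 0.30, with limma BH-adjusted p between 0.210 and 0.933. The cytokines Ifng and Il4 had −0.34 and 0.20 (limma, BH-adjusted p = 0.267 and 0.406). Il17a stayed under the filter, between 0 and 0.13 FPKM in lean libraries and listed at 0 in the obese ones. Of 21 Th1 and cytotoxic genes, 1 rose over all genes and over the list alone while the list lay lower (relative median −0.19; camera, BH-adjusted p = 0.00816; BH-adjusted p = 0.633 with an estimated correlation). Its means overlapped between groups, at 4.70 to 5.15 in lean and 4.83 to 4.93 in obese libraries on the log2 scale. Cytotoxic genes are also expressed by NK cells, whose markers lay lower too (relative median −0.45). The gene that rose was Gzmk, a granzyme, with 14.0 ± 4.79 FPKM in lean and 35.4 ± 3.66 FPKM in obese libraries (SD, n = 3 each), a log2 difference of 1.34 ± 0.22 (SE; limma, BH-adjusted p = 0.0113). Of 8 Th2 genes, 1 rose (2 over the list alone): Pparg, a nuclear receptor of lipid metabolism also found in macrophages, with a log2 difference of 1.08. Of 20 regulatory T cell genes, 1 rose (4 when adjusted over the list alone), Nrp1, a semaphorin receptor, with 0.65. Of 18 follicular helper genes, 2 rose (5 when adjusted over the list alone), Pdcd1 and Sostdc1, the latter with 0.76. No Th17 gene of 9 passed over all genes or over the list alone, and Tmem176b had 0.32. The Th2, Th17, regulatory and follicular lists did not pass with camera (BH-adjusted p = 0.301, 0.647, 0.139 and 0.132). The Th1 list did not pass without lean 1 or lean 3 or with the B cell marker covariate, the regulatory list passed without lean 1 and the follicular list without obese 1, with camera BH-adjusted p of up to 0.158 for the first and of 0.00635 and 0.0286 for the others. Nrp1 did not pass without lean 2, obese 2 or obese 3, and Sostdc1 did not without lean 1, lean 2 or obese 3 (limma, BH-adjusted p up to 0.0839).

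**Figure D2:**
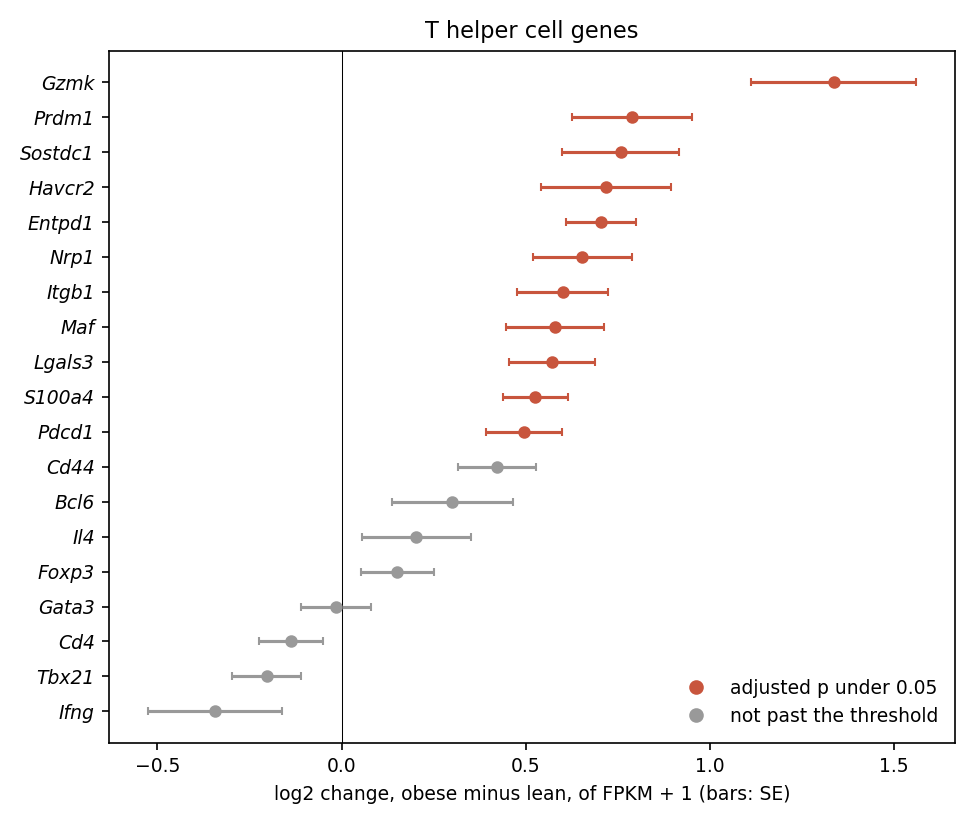
Log2 difference, obese minus lean, of log2(FPKM + 1) for helper T cell genes, with points for the estimate and bars for limma's SE of the difference (3 libraries per group). Gzmk, at 1.34, lies farthest to the right, and the regulators Tbx21, Gata3, Foxp3 and Bcl6 are not past the threshold.

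Heat shock genes lay lower in obese libraries. Of 14 tested, 5 fell and none rose, and 11 fell when adjusted over the list alone. Dnajb1, a co-chaperone, fell from 228.3 ± 21.7 to 75.4 ± 13.0 FPKM (SD, n = 3 each), a log2 difference of −1.59 ± 0.12 (SE; limma, BH-adjusted p = 4.02e-04). The neighbouring Hspa1a and Hspa1b, near-identical copies of the inducible HSP70 gene whose reads can be shared, together stood at 497.1 ± 122.4 FPKM in lean and 143.0 ± 64.2 FPKM in obese libraries (SD, n = 3 each). Their single log2 differences were −1.96 and −1.79. Bag3, a partner of HSP70, had −1.26. The relative median was −1.01 (camera, BH-adjusted p = 9.40e-15; BH-adjusted p = 0.315 with an estimated correlation), and the list mean was highest in lean 3, at 7.40 on the log2 scale against 6.54 and 6.62 in the other lean libraries. The list median, −0.90 before subtracting that of all genes, ranged from −1.12 to −0.55 when 1 library was left out, weakest without lean 3, and the list passed in each of these fits. Hspa1a did not pass without lean 1, lean 2 or obese 1 (limma, BH-adjusted p up to 0.0793).

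Immediate early genes, which respond within minutes to signals and to cell handling, went both ways. Of 26, 1 rose and 1 fell (2 and 1 when adjusted over the list alone), namely the phosphatase genes Dusp2 (log2 difference 0.52) and Dusp5 (−0.44), of which the first did not pass without lean 1, lean 2, obese 1 or obese 2 and the second without lean 1, obese 1 or obese 3 (limma, BH-adjusted p up to 0.0970). The list did not pass (camera, BH-adjusted p = 0.15), but passed without obese 3 (BH-adjusted p = 0.00229), with the B cell marker covariate (0.0145) and with the erythroid marker covariate (3.37e-06), each in the lower direction. Its median of 0.06 was positive while the camera direction was down. The erythroid marker covariate correlates with the group at 0.944, so it leaves little of the group difference to test. ER stress and folding genes (17) had no called member over all genes or over the list alone and a relative median of 0.16, with Xbp1 and Pdia6 at log2 differences of 0.45 and 0.26. Plasma cells express such genes too, and the means of the plasma cell and ER stress lists were both highest in obese 3, at 5.76 and 6.17 on the log2 scale. That list passed with camera (BH-adjusted p = 0.0387; BH-adjusted p = 0.725 with an estimated correlation) but not without lean 1, lean 2, obese 2 or obese 3 (BH-adjusted p up to 0.241), nor after median-of-ratios scaling (0.0934) or with the B cell marker covariate (0.158). Glucocorticoid-responsive genes (9) and amino acid and ATF4 genes (17) did not pass (camera, BH-adjusted p = 0.851 and 0.301), except the first with the erythroid marker covariate (0.0301). In the first, Il7r and Per1 had log2 differences of 0.47 and 0.27, and no member passed over all genes or the list alone. In the second, Asns, asparagine synthetase, rose over all genes and over the list alone, with 1.10 (limma, BH-adjusted p = 0.0250), but not without lean 2 or lean 3 (up to 0.0943).

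Ribosomal protein genes shifted lower as a group by a small amount. Of 78 tested, 3 fell and none rose, and 55 fell when adjusted over the list alone, with a relative median of −0.42 (camera, BH-adjusted p = 2.83e-41; BH-adjusted p = 0.315 with an estimated correlation). Rpl37 and Rpl28, of the large subunit, each had a log2 difference of −0.43 and passed in no leave-one-out fit but that without lean 3 (limma, BH-adjusted p up to 0.177). Rps27 had −1.72 and did not pass without any 1 lean library or obese 3 (up to 0.148). Its reads can be shared with the near-identical Rps27rt, which had 0.10, and both together stood at 10771 ± 776 FPKM in lean and 8872 ± 1675 FPKM in obese libraries (SD, n = 3 each), a log2 difference of −0.30. Nuclear respiratory chain genes (64) had no called member over all genes or the list alone and a relative median of −0.11 (camera, BH-adjusted p = 6.43e-05; BH-adjusted p = 0.640 with an estimated correlation), with Uqcrb and Ndufs7 at 0.28 and −0.26. Before subtracting that of all genes, the median was −0.01. The means of this list overlapped between groups, at 6.81 to 6.96 in lean and 6.81 to 6.93 in obese libraries on the log2 scale.

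Cell cycle genes lay higher in obese libraries. Of 26, 6 rose and none fell, and 17 rose when adjusted over the list alone. Mki67, a marker of dividing cells, rose from 1.28 ± 0.386 to 6.03 ± 3.44 FPKM (SD, n = 3 each), a log2 difference of 1.53 ± 0.30 (SE; limma, BH-adjusted p = 0.0209). Rrm2 and Tk1, of nucleotide synthesis, and Ccne1, a cyclin, rose by 1.15, 0.89 and 0.72. Red cell precursors divide as well, and the erythroid marker mean was 6.11 to 8.37 on the log2 scale in obese libraries against 2.98 to 3.63 in lean ones. The relative median was 0.51 (camera, BH-adjusted p = 8.60e-06; BH-adjusted p = 0.633 with an estimated correlation). Mki67 and Ccne1 did not pass without lean 1 or lean 2, Rrm2 without lean 1, lean 2 or obese 1, and Tk1 without lean 2 (limma, BH-adjusted p up to 0.0949). None of these genes passed with the B cell marker covariate (limma, BH-adjusted p = 0.101, 0.101, 0.128 and 0.0660), where their log2 differences were 1.28, 0.65, 0.97 and 0.73. The means of the B cell and cell cycle lists were both highest in obese 3, at 5.58 and 4.64 on the log2 scale.

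Of 26 interferon-stimulated genes, 3 rose, and 8 rose and 1 fell when adjusted over the list alone. Oas1a, an antiviral enzyme, rose from 20.4 ± 0.749 to 33.0 ± 1.49 FPKM (SD, n = 3 each), a log2 difference of 0.67 ± 0.08 (SE; limma, BH-adjusted p = 0.00172). Rsad2, the antiviral protein viperin, rose by 2.66 and stood at 15.4, 4.18 and 19.2 FPKM in obese 1, obese 2 and obese 3, lowest in obese 2, as the globins were. Slfn5 rose by 0.44 and passed in no leave-one-out fit but that without lean 3 (limma, BH-adjusted p up to 0.152). Of 16 NF-kB targets, Cd83 (log2 difference 0.57) and Bcl2a1b (0.53) rose, and 3 rose when adjusted over the list alone. Bcl2a1b belongs to a family of near-identical copies, so its value is uncertain, and Cd83 did not pass without lean 1 or lean 2 (limma, BH-adjusted p up to 0.0626). Neither list passed with camera (BH-adjusted p = 0.322 and 0.166).

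Cholesterol efflux and antioxidant genes lay higher in obese libraries, together with the macrophage marker mean, which was at least 5.74 in obese and at most 4.68 in lean libraries. Of 8 efflux genes, 3 rose (6 when adjusted over the list alone) and none fell. Apoe, a lipid carrier that macrophages secrete, rose from 165.1 ± 38.2 to 428.0 ± 62.5 FPKM (SD, n = 3 each), a log2 difference of 1.38 ± 0.16 (SE; limma, BH-adjusted p = 0.00184). Nr1h3, the sterol-sensing receptor LXR-alpha, and Scarb1, a lipoprotein receptor, rose by 1.27 and 0.69. Of 18 antioxidant genes, 2 rose (12 when adjusted over the list alone) and none fell. Hmox1, the haem-degrading enzyme, rose from 111.0 ± 12.4 to 275.4 ± 21.1 FPKM (SD, n = 3 each), a log2 difference of 1.31 ± 0.10 (SE; limma, BH-adjusted p = 4.00e-04). Gpx1, a glutathione peroxidase abundant in red cells, rose by 0.64 and passed in no leave-one-out fit but that without obese 2 (limma, BH-adjusted p up to 0.0904). Relative medians were 0.29 for efflux (camera, BH-adjusted p = 0.00328) and 0.17 for antioxidant genes (camera, BH-adjusted p = 5.62e-04), each with a BH-adjusted p = 0.315 with an estimated correlation. The estimated correlation was −0.074 for efflux genes, under the preset 0.01, and 0.064 for antioxidant genes. Correlation between genes therefore does not account for the lost call of the efflux list. With fry both lists passed (fry, BH-adjusted p = 0.00127 and 0.0115).

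Genes of lipid and glucose metabolism showed few changes. No gene of cholesterol synthesis and uptake (23) passed over all genes or the list alone, while the list lay lower (relative median −0.22; camera, BH-adjusted p = 3.38e-05; BH-adjusted p = 0.315 with an estimated correlation). Its means overlapped between groups, at 3.61 to 3.67 in lean and 3.47 to 3.64 in obese libraries on the log2 scale. Fdps, of sterol synthesis, had a log2 difference of −0.33. Of 23 fatty acid oxidation genes, 2 rose (4 when adjusted over the list alone): the fatty acid transporter Cd36, also present on macrophages and red cell precursors, by 1.88 (limma, BH-adjusted p = 0.00448), and Acsl1 by 0.68, which passed in no leave-one-out fit but that without obese 2 (up to 0.158). Cpt1a, the entry step of mitochondrial fatty acid oxidation, had a log2 difference of 0.43 (limma, BH-adjusted p = 0.125), which passed without lean 3 (BH-adjusted p = 0.0383). Of 22 glycolysis genes, Eno3 rose by 0.41 over all genes and no gene passed when adjusted over the list alone. It passed in no leave-one-out fit but that without lean 2 (limma, BH-adjusted p up to 0.137). No gene of fatty acid synthesis (15) passed over all genes or over the list alone, with Fads2 at 0.58, Fasn at −0.24 and Acaca at −0.07. Insulin, leptin and adipokine signalling genes (16) and circadian clock genes (12) also had none in either count. Jak2, Igf1r and Insr, the insulin receptor, had 0.51, 0.29 and 0.18, and Nr1d2 and Clock had 0.33 and 0.22. Lepr, the leptin receptor, lay under the filter, at 0.05 to 0.12 FPKM in lean and 0.15 to 0.16 FPKM in obese libraries. The lists of fatty acid oxidation, glycolysis, fatty acid synthesis, insulin signalling and clock genes did not pass with camera (BH-adjusted p = 0.166, 0.319, 0.167, 0.909 and 0.941). For fatty acid synthesis, amino acid and ATF4, clock and dendritic cell genes the median was above 0 and the camera direction was down.

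**Figure D3:**
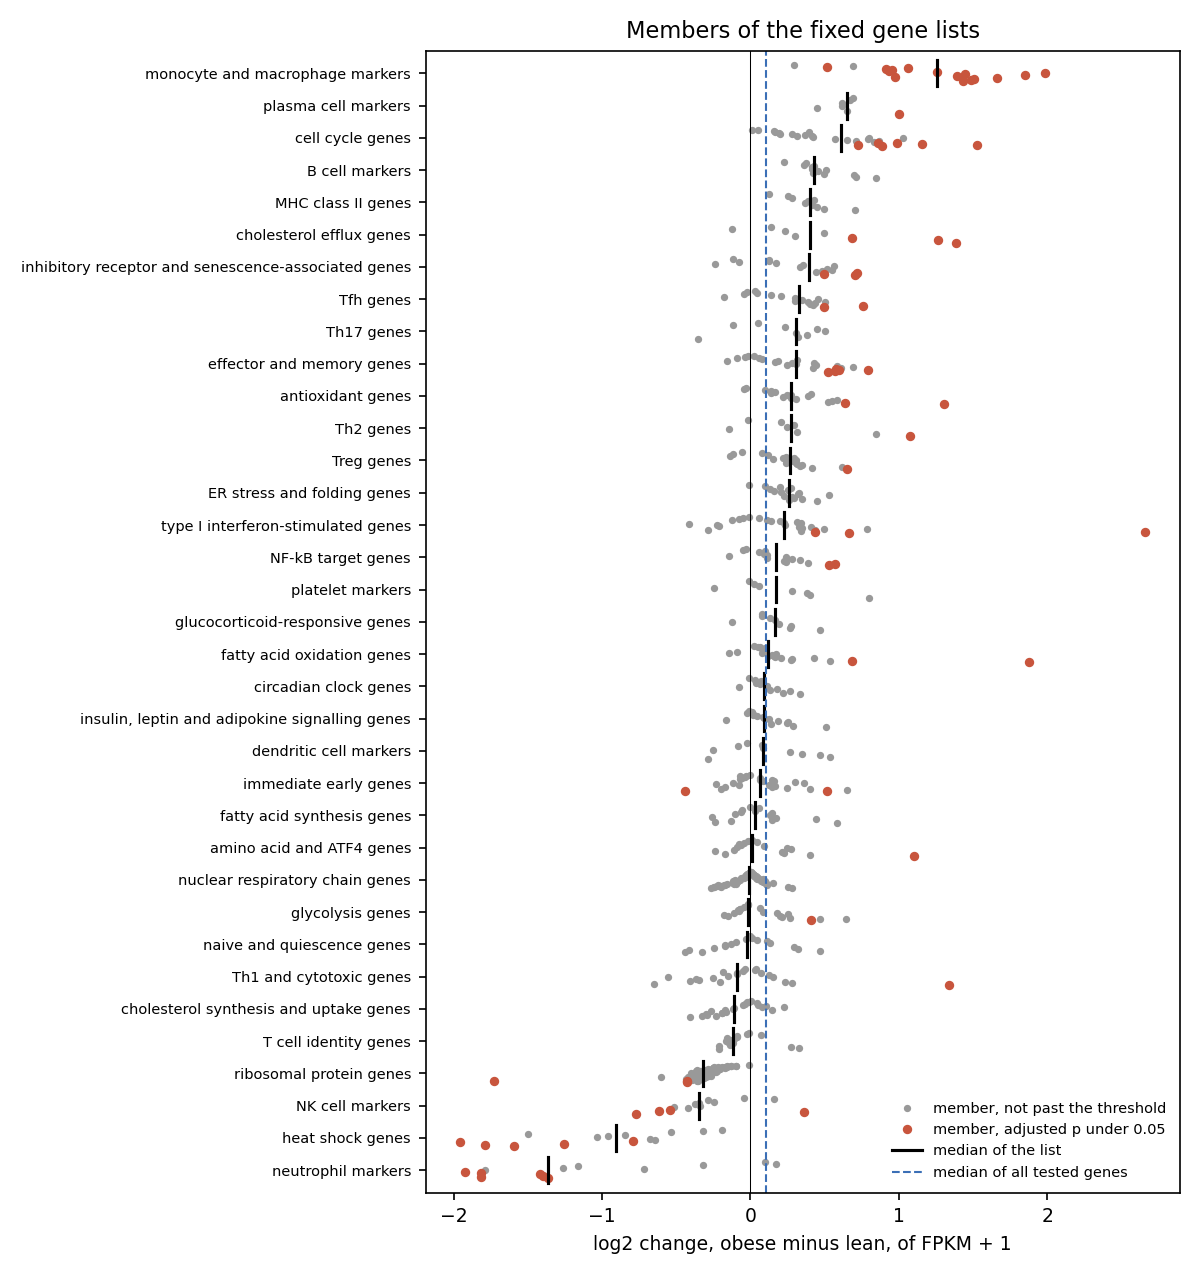
Log2 difference, obese minus lean, of log2(FPKM + 1) for each tested member of 35 of the 36 tested lists, with a point per gene, a vertical bar for the list median and a dashed line for the median of all tested genes at 0.10. Erythroid markers, with a list median of 4.98, lie outside the range and are left out. Macrophage markers lie highest, with a list median of 1.26, and neutrophil markers lowest, at −1.36.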

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

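The covariate fits and the removal of other cell types' markers were chosen after seeing the data. Called genes, 678 (622 higher, 56 lower), numbered 368 (344 and 24) with no filter on low values, 352 (316 and 36) with at least 5 FPKM, 607 (434 and 173) after median-of-ratios scaling, 434 (322 and 112) after quantile normalization, 985 (940 and 45) when scaled without immunoglobulin, haemoglobin and mitochondrial genes, 216 (199 and 17) with a 2-fold minimum and 3116 (2507 and 609) with library weights, which ranged from 0.282 to 4.19. The scaling without immunoglobulin, haemoglobin and mitochondrial genes left out 11 genes. The listed mitochondrially encoded genes and Ighm, Ighd, Igha and Ighg1 were not among the values, so this scaling did not remove them. Leave-one-out fits gave 318 to 698 genes, 299 to 601 higher and 19 to 97 lower. The labels do not say whether the replicate numbers pair the libraries. Deviations of same-numbered libraries correlated at 0.032, 0.061 and 0.193, against −0.170 to 0.160 for differently numbered ones, which does not settle it. A replicate block gave 1015 genes (866 and 149) and 18 lists. With pseudocount 0.1, TPM scaling, no intensity trend or a robust variance model, counts stayed within 1.5 times, at 668 to 752 genes. The B cell marker covariate left 288 genes (265 and 23), and leaving out markers of other cell types gave 670. No called gene changed sign in any of these fits. The erythroid marker covariate, which correlates with the group at 0.944 and so leaves little of the group difference to test, gave 0 called genes (0 higher, 0 lower), with 184 at an unadjusted p under 0.05 by limma, and 94 of the 678 genes changed sign. Among named genes these were Hba-a1 (−0.024), Alas2 (−0.44), Rhd (−0.29), Cd36 (−0.081), Rsad2 (−0.58), Mki67 (−0.055), Rrm2 (−0.25), Gpx1 (−0.30), Ncr1 (0.12) and Acsl1 (−0.057). Lists past the threshold, 18, numbered 1 with an estimated correlation, 4 with fry, 13 to 21 in leave-one-out fits, 14 with the B cell covariate, which ended the calls of the naive, Th1, inhibitory receptor, ER stress and T cell identity lists (medians 0.01, −0.02, 0.36, 0.20 and −0.05, against −0.02, −0.09, 0.40, 0.26 and −0.12) and gave one to the immediate early genes, and 11 with the erythroid covariate. Under the last, list directions reversed, by median or by the camera direction, for naive (0.16), Th1 (0.29), cell cycle (0.035), cholesterol synthesis (0.15), nuclear respiratory chain (0.10), T cell identity (0.24), B cell (−0.69), MHC class II (−0.42) and erythroid (0.081) lists. The 4 lists past the threshold with fry were macrophage (fry, BH-adjusted p = 3.50e-04), cholesterol efflux (0.00127), antioxidant (0.0115) and erythroid (0.0443). Except where fewer genes, fewer libraries or the near collinear covariate explain a count by construction, the cause was not tested. Count-based tests planned for expected counts were not run, since no counts were among the values used here. Depth is unknown, so which low genes it limits cannot be said. Of the 61 named genes past the threshold, 49 passed after median-of-ratios scaling and 36 with the B cell covariate. Those lost to the scaling were S100a4, Cd83, Lgals3, Itgb1, Dusp2, Pdcd1, Tyrobp, Gpx1, Eno3, Havcr2, Acsl1 and Slfn5, with BH-adjusted p of 0.0508 to 0.221. Those lost to the covariate were Tk1, Bag3, Ccne1, Cd83, Mki67, Asns, Nrp1, Lgals3, Jchain, Prdm1, Rrm2, Pdcd1, Sostdc1, Tyrobp, Dusp5, Gpx1, Rpl37, Ncr1, Klra4, Eno3, Rps27, Rpl28, Havcr2, Acsl1 and Slfn5, with limma BH-adjusted p of 0.0607 to 0.224. Their log2 differences were 0.735 to 1.09 times those of the main fit and their SE 0.863 to 1.29 times, so these losses do not show that B cell RNA accounts for the genes. Among lists past the threshold, leaving out 1 library moved a median by more than 1.5 times for heat shock (−0.90 to −0.55), cholesterol synthesis (−0.11 to −0.05), ER stress (0.26 to 0.15) and T cell identity (−0.12 to −0.03), and for the naive, Th1 and nuclear respiratory chain lists, whose medians took either sign. Over all named genes and alternatives, 1773 results stayed on the same side of the threshold, of which 46, past it in neither fit, had the opposite sign, and 291 lost the call, 44 gained one and 10, called in the main fit, had the opposite sign without passing.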

Other observations

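All tests of explanations here were chosen after the result was seen, except the counts over other splits of the libraries. The genes of this paragraph were named after their values were seen. Spic and Vcam1 are members of the fixed list of macrophage markers and are already counted there. Spic, a transcription factor of red pulp macrophages, rose from 6.51 ± 1.74 to 25.8 ± 3.89 FPKM, Vcam1 from 21.3 ± 7.26 to 84.7 ± 8.31 FPKM, and the iron exporter Slc40a1 from 18.2 ± 3.18 to 58.7 ± 5.38 FPKM (SD, n = 3 each). Cd5l, a protein secreted by macrophages, had a log2 difference of 2.01 ± 0.14 (SE; limma, BH-adjusted p = 4.00e-04), and Hpgd and Fabp4 had 1.62 and 1.74. Epor, the erythropoietin receptor, and Tfrc, the transferrin receptor, both of red cell precursors, had 1.86 and 1.63 (limma, BH-adjusted p = 0.00850 and 0.0226). Tnfsf9, a co-stimulatory ligand, fell from 9.41 ± 0.460 to 3.96 ± 0.161 FPKM (SD, n = 3 each; log2 difference −1.07; limma, BH-adjusted p = 5.54e-04). The Y-linked gene Ddx3y was present in both groups, at 6.15 ± 1.78 and 8.19 ± 1.57 FPKM (SD, n = 3 each).

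The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 678 genes and the highest of the other 9 splits called 0, so 1 of the 10 gave as many. For lists, 2 of the 10 splits gave as many as the real 18, and the highest of the other splits gave 19 (lean 1, obese 1 and obese 3 against the rest), with a range of 6 to 19, so the real split did not give the most lists.

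Erythroid and macrophage markers were higher and neutrophil markers lower in obese libraries, although CD4+ T cells had been purified by flow cytometry. A lower share of T cells would raise the markers of every other cell type alike. The median of the macrophage markers exceeded that of the neutrophil markers by 2.62 on the log2 scale. This difference restates the pattern and is no separate test, but the opposite directions argue against a lower share of T cells as the whole cause. Red cell RNA from 1 source entering the obese libraries in different amounts stays open: erythroid markers were lower in obese 2 than in obese 1 by a median log2 ratio of −2.53, with an SD over markers of 0.80, and Klf1 and Car2 stood apart at −0.49 and −1.09. Macrophages or their RNA in the obese libraries also stay open, since the share of tested macrophage markers called higher, 88.2%, restates the pattern and tests no cause of it. A change of the spleen with the diet, such as more red cell precursors and macrophages, may underlie either and was not tested.

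Heat shock genes were lower in obese libraries, which may reflect the cells or their handling. The scale of the deposited FPKM does not account for it, since the list's median was −1.05 after median-of-ratios scaling. The list passed at the preset correlation between genes and not with an estimated one (camera, BH-adjusted p = 0.315). Handling that lowered both sets of genes in obese libraries would show as a fall of the immediate early genes, which went both ways around a median of 0.0628. That list passed as lower without obese 3 and with the B cell marker covariate, so the question is not settled. Handling that left the immediate early genes unmoved cannot be told apart from an effect of the diet. Within the lean group, lean 3 had the highest list mean, and without it the median was −0.55, so the level also varied between libraries of the same diet. Obese 3 was likewise highest in its group, at 6.23 against 5.59 and 5.73 on the log2 scale. Whether libraries of 1 number shared handling is not given. Hspa1a and Hspa1b went the other way in lean 3, where they were lowest among lean libraries, at 105.0 and 250.7 FPKM.

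Effector and memory genes were higher in obese libraries. B cell RNA carried into some libraries is argued against as the whole cause, since with B cell markers as a covariate the list's median was 0.41 and it still passed (camera, BH-adjusted p = 0.00356). Both this call and that of the main fit were made at the preset correlation between genes. In the main fit the list did not pass with an estimated one (camera, BH-adjusted p = 0.633). That loss need not come from correlation, since the cholesterol efflux list lost its call at an estimated correlation of −0.074. Macrophages or their RNA could account for the higher effector and memory genes and cannot be told apart from a change in the T cells. The macrophage marker mean correlates with the group at 0.997 and, as a covariate, would leave no group difference to test. A shift of the T cells towards memory with the diet also stays open, and it was not tested.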
